A study of Drosophila melanogaster with 2 samples.

How the data were processed

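The series measured DNA bound by Adf1 fused to enhanced green fluorescent protein in whole Drosophila melanogaster embryos collected at 0 to 24 h, in 2 biological replicates with 1 library each. Per the labels, the flies were transgenic and sonicated fragments of 200 to 800 bp were sequenced. The sample descriptions name an antibody against green fluorescent protein, while the antibody field gives Adf1, which was read as the target. The deposited peak lists used were, for each replicate, a thresholded and a ranked list and, for both replicates together, a conservative and an optimal thresholded list with their ranked lists, all on Release 6 of the genome (dm6). Per the deposited file lists, they were derived by the authors from alignments of the libraries and a control file. The aligner, the peak caller and their versions are not given in the sources used here. Lists were ranked by the irreproducible discovery rate (IDR), which estimates how far the rank of a peak is repeated between sets of calls.

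The score of each peak is, per the deposited file type, a scaled IDR made by the authors, from 0 to 1000. In the ranked lists the minimum score of the thresholded lists corresponds to a global IDR of 0.01. The signal of each peak is the authors' peak-caller value, whose scale is not stated; it ranks and describes peaks and was entered in no model. The deposited -log10 values (of the caller's q value, and of the local and global IDR in ranked lists) were used for reading the lists only. The summit offset, in bp from the peak's start, is the authors' and gave the summit position. No read counts or alignments were used here, so no depth per replicate is given, and precision was described by counting intervals alone.

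The conservative list, called across the replicates, was the main list and is named the replicate-supported list. Summits on the 7 arms 2L, 2R, 3L, 3R, 4, X and Y were kept, which left out 1 peak of replicate 1. Identical intervals with several summits were kept as separate summits. Genes were the 13968 protein-coding genes of the Ensembl annotation of BDGP6.54, release 115, with 19275 distinct TSSs, a TSS being the 5' end of any annotated transcript. A gene was bound if a summit lay within 500 bp of any of its TSSs. Features were assigned in the order TSS region, 5' UTR, 3' UTR, coding sequence, intron or non-coding exon, and outside genes.

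Replicate overlap was the share of peaks overlapping the other's list by at least 1 bp, with Wilson intervals. Clustering at TSSs was tested with 1000 shuffles of positions within each arm, and arms with exact binomial tests against length. The 27 gene lists and 17 motifs were written from general knowledge of the fly. Lists were tested with Fisher's exact test against all other genes, and also against 10000 random lists matched on 10 classes of gene length and on TSS number up to a class of 5 or more. Motifs and 6-mers were tested with Fisher's exact test in windows of 50 bp either side of the summit (101 bp) against windows of equal width centred 500 bp to each side. Other backgrounds were genomic windows of equal GC content and, for summits near a TSS, TSSs of genes with no peak within 1000 bp at equal distances. All tests were two-sided with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Odds ratio intervals are 95% intervals on the log scale, with 0.5 added to every cell where a count was 0.

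Named genes followed a fixed rule: the gene with the nearest TSS for each of the 20 peaks with the highest signal, all genes of the list of known targets, and up to 4 bound members of each other list with the highest signal. The 10 6-mers with the largest odds ratio, among those called and in at least 2% of summit windows, were named. Results for some genes that the rule names are not reported here. In the lists, 4 symbols had no match in the annotation and were left out (B, RpII215, madf-1 and Ald, whose gene is present as Ald1). The cytochrome P450 list took symbols by their opening letters and so held the cyclophilin genes Cyp1 and Cyp40, and the cuticle list held the accessory gland protein genes Acp33A and Acp76A.

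Alternatives tried were the optimal list, the stronger part of each list by signal, each replicate's own list, other overlap rules, other distances, nearest-gene assignment, matched lists, other windows and backgrounds, and TSS number as the null for arms. Others were added after seeing the data: peaks past the threshold that the thresholded list omits were put back, the cyclophilins were removed, 1 gene per 10 kb was kept in each list, and Adf1 was removed from the lists. The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

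The methods were tested on simulated data. A planted share near TSSs of 47.8% was recovered as 47.6%, and 0 of 20 uniform placements were called. A planted excess on X was called, and in 20 uniform placements 1 arm was called. Planted gene lists were called in 99.2% of cases and unchanged lists in 0.185%. Only larger lists were planted, with binding raised far above the share of all genes. Power for small lists such as known targets, MADF and Hox genes, or for smaller differences, was not simulated. When gene length and TSS number alone set the binding, Fisher's test called 8.89% of lists and matched lists 0%. With nothing planted, 0 motifs and 0 6-mers were called, and with a planted triplet the leading 5 6-mers all lay inside it. A planted overlap of 79.2% was found as 79.8%.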

Results

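Binding of the transcription factor Adf1 was mapped across the genome in whole Drosophila melanogaster embryos aged 0 to 24 h. Adf1 is a DNA-binding protein of the MADF domain family, known for acting on the distal promoter of the alcohol dehydrogenase gene Adh. The flies carried Adf1 fused to green fluorescent protein, and chromatin was precipitated with an antibody against that tag and sequenced (ChIP-seq). The series holds 1 group of 2 biological replicates and no control sample, so no groups were compared. The values used are peak lists, which hold no read counts, and the sequencing depth of each replicate is therefore unknown. Intervals below are 95% intervals for counting error only, and neither peaks nor genes are biological replicates.

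The replicate-supported list held 4370 summits in 4117 peak intervals, which merged into 3864 separate regions on the Release 6 genome. Its median interval was 510 bp wide and its widest, over Adf1 itself on 2R from 6661825 to 6664155, was 2331 bp. Replicate 1's own list held 3127 peaks and replicate 2's own list 6003. The optimal list, a longer list for both replicates together, held 5607. It held 4061 (92.9%) of the replicate-supported summits at identical positions, so it does not contain that whole list. The peak signal is the authors' value on a scale that is not stated, and it was used only to rank and describe peaks within 1 list; its median in the replicate-supported list was 150.6.

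All 20 of the strongest replicate-supported peaks, among them those at Adf1, abd-A, Lim1, btd and brk, were present in each replicate's own list. The question here was how far the replicates called the same regions. Of replicate 1's 3126 peaks on the 7 chromosome arms, 2795 (89.4%, 88.3 to 90.4%) overlapped a peak of replicate 2, against 3.28% for shuffled positions. Of replicate 2's 6003 peaks, 3160 (52.6%, 51.4 to 53.9%) overlapped one of replicate 1, against 1.98% for shuffled positions. Overlap followed peak strength: it was 99.5% among the strongest peaks of replicate 1 and 74.0% among its weakest, and 95.7% and 27.9% in replicate 2, with each list divided into 4 equal parts by signal. Of the 331 peaks of replicate 1 without a partner, 295 (89.1%) overlapped a peak below the threshold in the other's ranked list, and of the 2843 of replicate 2, 2436 (85.7%) did. Overlap of all peaks with that longer list was 98.9 and 93.2%, against 27.6 and 16.4% for shuffled positions. Across the 4271 summits matched within 250 bp in each replicate's ranked list, signal had a Spearman correlation of 0.706, a description across peaks that are not independent replicates and that the authors had selected for like ranks, so that it depends on that selection. Among the overlapping peaks of replicate 1's own list, the median distance to the nearest summit of replicate 2 was 24 bp.

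The strongest peaks lay at Adf1 itself and, among others, at some regulators of development. The highest signal, 8099.6, was in the wide peak over Adf1 (FBgn0284249), with its summit at 2R position 6663139, in an intron or non-coding exon 869 bp downstream of the nearest transcription start site (TSS). The next, at 3814, lay on 3R from 16847071 to 16847671, and the nearest protein-coding start was that of the Hox gene abd-A (FBgn0000014), 17331 bp away. Signals between 3096 and 3544 followed at Eglp4, an aquaporin family gene, Svil, ssp3, CG3036, the nuclear receptor gene ftz-f1 and CG31275. The peak at not, which encodes a histone H2B deubiquitinase, had its summit in the 5' UTR with a signal of 2921. Another lay 1720 bp upstream of the Hox gene Antp, with a signal of 2852. Others of the 20 were at Lim1, CG31729, btd, CAP, Kr-h1, sgg, CG4629 and brk, of which Lim1 and btd encode developmental transcription factors, sgg the Drosophila glycogen synthase kinase 3, and brk a repressor of Dpp target genes. Of these 20 summits 12 were within 500 bp of a TSS, 5 were more than 5 kb from any, and the weakest had a signal of 2537. Summits far from a start are named here by the nearest gene only, and no link to that gene's activity was measured.

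Summits clustered at transcription start sites. Those at CG31729, CG3036, CG4629 and Kr-h1 lay 50, 93, 98 and 100 bp from a TSS, while the one nearest to CG31275 lay 12847 bp away. In all, 2544 of 4370 summits (58.2%, 56.7 to 59.7%) were within 500 bp of a TSS of a protein-coding gene. Peaks shuffled within their arm gave 11.5% ± 0.497 (SD over 1000 shuffles), with a highest value of 12.9%, and the permutation p of 0.002 (two-sided) was the smallest these shuffles can give. The share was 45.9% within 200 bp and 67.1% within 1000 bp. Of the other summits, 1165 (26.7% of all) lay in introns or non-coding exons, which make up 39.3% of the sequence under the same scheme. These are shares of all summits and of all sequence. TSS regions took 58.2% of summits in 11.5% of the sequence, which lowers the share of summits left for every other class. The intron share is therefore no sign that introns held few of the summits away from a TSS. Only 55 (1.26%) lay in coding sequence, which makes up 13.3%, and 26 (0.595%) in 3' UTRs, which make up 5.22%, while 57 (1.304%) lay in 5' UTRs, which make up 0.800%. A further 523 summits (11.97%) were outside protein-coding genes, and 283 (6.48%) were at least 10 kb from any TSS.

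**Figure D1:**
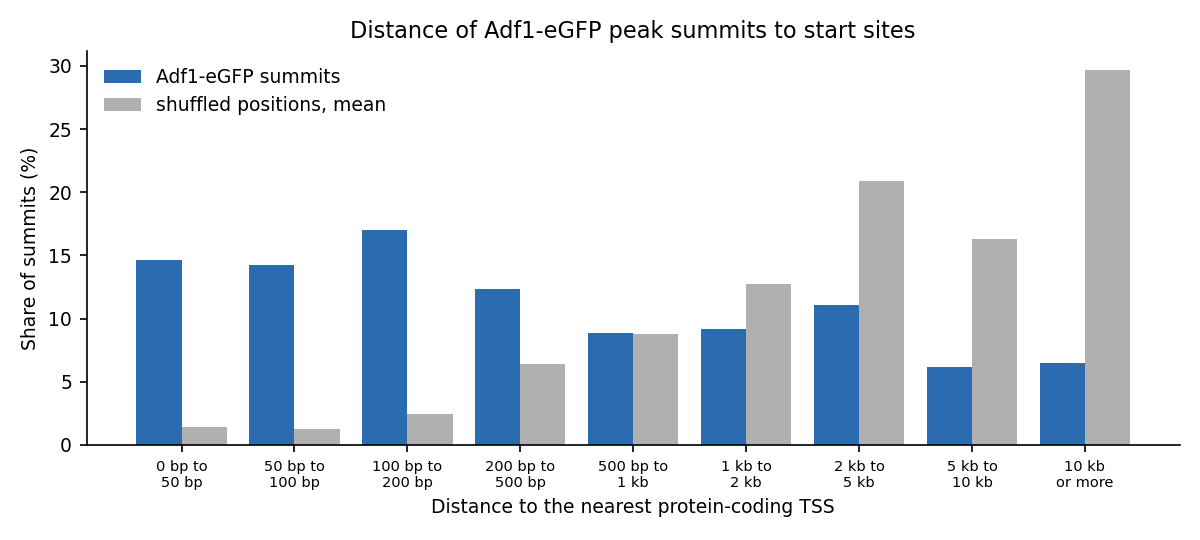
Percent of the 4370 replicate-supported summits (observed) and mean percent after shuffling positions within their arm (shuffled) in each class of distance to the nearest TSS, in bp. Summits under 50 bp from a TSS made up 14.6% against 1.40% when shuffled, and those at 10 kb or more 6.48% against 29.7%.

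Lim1, btd, sgg and brk, all at peaks among the strongest 20, are on the X chromosome. The X held 957 summits (40.7 per Mb) against 748.0 expected from its length, a ratio of 1.28 (exact binomial test, two-sided, adjusted over 7 arms, p = 1.53e-15). The small chromosome 4 held 14 against 42.8 expected (ratio 0.327, adjusted exact p = 1.13e-06). None lay on the Y, where 116.5 were expected (adjusted exact p = 5.62e-51). Arm 3R held 942, a ratio of 0.924 (adjusted exact p = 0.00973), which was no longer past the threshold in replicate 2's own list alone (0.959) or after peaks missing from the final list were put back (0.988). Arms 2L, 2R and 3L, with 759, 820 and 878 summits, did not differ from their length share. In replicate 2's own list, however, 2R was above it (1.08, adjusted exact p = 0.005), and the ratio of chromosome 4 fell to 0.131 in replicate 1's own list. Against the number of start sites on each arm instead of its length, 2L (0.924) and 2R (0.918) fell below expectation, and the directions on X, 4 and 3R were unchanged. How many reads from each arm could be placed uniquely was not measured, which bears most on the repeat-rich Y and 4 and on repeated genes such as the histone array.

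Of the genes known from earlier work as targets of Adf1, or Adf1 itself, 5 of 6 had a summit within 500 bp of a TSS. At Adh (2L), the summit at 14616135 was 132 bp from a TSS with a signal of 585.7, and an Adf1-type triplet match, GCTGCCGTCG, began at 14616134. The annotated gene begins at 14615552 on the plus strand, so this TSS is an internal one and not the gene's outermost start. At Ddc, the dopa decarboxylase gene, the summit was 57 bp away with a signal of 233. At Fas2, a neural cell adhesion gene, it was 88 bp away with a signal of 192. Replicate 1's own list had no summit within 100 bp of that one. At the start of Antp the signal was 876, and at that of Adf1 it was 1606 at a summit 52 bp away. At stau, which encodes an RNA-binding protein, the nearest summit of the list was 2675 bp away. The odds ratio against the other genes was 21.5 (2.51 to 184; Fisher's exact test, two-sided, adjusted over 27 lists, p = 0.00296), but this list did not differ from random lists matched on gene length and start sites (1.88 bound on average, adjusted permutation p = 0.0616). The odds ratio was 43.1 in replicate 2's own list, where stau had a summit with a signal of 43.8, and 12.1 in replicate 1's; in the optimal list stau had one with a signal of 86.2.

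Across the genome 2636 of 13968 protein-coding genes (18.9%) had a summit within 500 bp of a TSS, and this is what "bound" means for the lists below. Of 42 developmental regulators known as Polycomb targets, 32 (76.2%, 61.5 to 86.5%) were bound, among them the T-box gene mid (signal 1527), the wing gene vg (1472), the forkhead gene fkh (1389) and the BMP ligand gene dpp (1349). The odds ratio was 13.9 (6.83 to 28.3; adjusted Fisher p = 3.10e-14), and matched random lists held 13.5 bound genes (adjusted permutation p = 0.0018, from an unadjusted p of 0.0002, the smallest that 10000 random lists can give). Of the 8 Hox genes, 5 were bound: abd-A (1834 at its own start), Antp, Abd-B (176), Dfd (170) and 1 more. Of 21 Polycomb group genes, 9 were bound, with Psc (1745), Su(z)2 (669), ph-p (632) and jing (337) the strongest. Gap and pair-rule genes were bound in 7 of 17 cases, among them run (536), hry, the gene hairy (373), cad (276) and odd (269). Components of BMP, Wnt, Hedgehog and EGFR signalling were bound in 17 of 35, with brk (2537), aop (1873) and pnt (1686) leading.

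The odds ratios of these latter lists were 7.18 for Hox (adjusted p = 0.0145), 3.23 for Polycomb group (0.0165), 3.01 for gap and pair-rule (0.0445) and 4.08 for signalling genes (2.92e-04), all by Fisher's exact test. None of the 4 differed from matched random lists, which held 3.37, 5.62, 3.54 and 11.7 bound genes. In replicate 2's own list alone, the Hox and the gap and pair-rule lists were not past the threshold (adjusted exact p = 0.136 for each), and the latter was not called in the optimal list or within 1000 bp either. Of all lists bound more often, 4 were still called when a summit had to be within 200 bp: known targets, Polycomb targets, signalling and cytosolic ribosomal protein genes. The others had odds ratios from 2.36 (synaptic and axon guidance genes) to 5.58 (Hox), with adjusted Fisher p from 0.0505 (Hox and synaptic) to 0.115 (MADF genes).

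**Figure D2:**
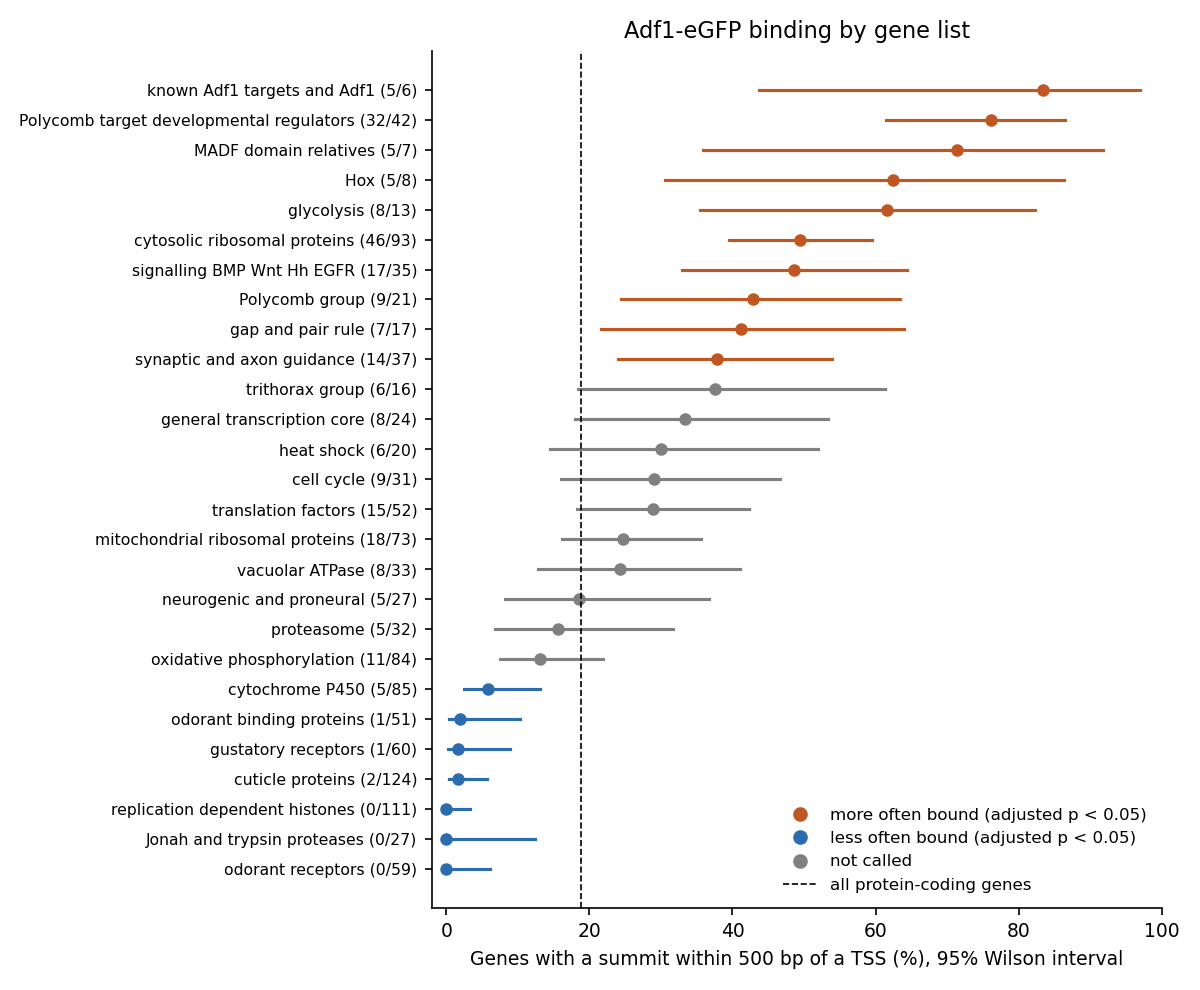
Percent of each gene list's members with a replicate-supported summit within 500 bp of a TSS, with 95% Wilson intervals; orange lists were bound more often and blue lists less often than other genes, grey lists were not called, and the dashed line is the share of all genes, 18.9%. Polycomb-target regulators stood at 76.2%, and odorant receptors, proteases and histones at 0.

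Synaptic and axon guidance, glycolysis and MADF genes formed further lists. Among 37 synaptic and axon guidance genes 14 were bound, including the adhesion gene Fas3 (1867), the synaptic vesicle chaperone gene Csp (916), the potassium channel gene Sh (722) and the scaffold gene dlg1 (283), an odds ratio of 2.63 (adjusted Fisher p = 0.0113). Matched random lists held 15.02 bound genes, slightly more than this list. Of 13 glycolysis genes 8 were bound, with Hex-A (2067), Ald1 (2031), Gapdh2 (574) and Eno (396) leading (odds ratio 6.90, adjusted p = 0.00248), against 4.22 in matched lists (adjusted permutation p = 0.0999). Relatives of Adf1 with a MADF domain were bound in 5 of 7 cases, among them Adf1, hng3 (148), Coop (129) and Dlip3 (104). Their odds ratio was 10.8 (adjusted p = 0.00802) and matched lists held 1.58 (adjusted permutation p = 0.0288), but 3 of 7 were bound in replicate 1's own list, which was not past the threshold (adjusted exact p = 0.0921), nor were 4 of 7 in the optimal list (0.0872) or 1 of 7 by the 2185 strongest summits (0.575).

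Cytosolic ribosomal protein genes were bound in 46 of 93 cases (49.5%, 39.5 to 59.4%), with modest signals, the highest being 363 at RpL7, 309 at RpL14, 308 at RpL41 and 263 at RpL34b. The odds ratio was 4.26 (2.83 to 6.42; adjusted Fisher p = 3.10e-10) and matched lists held 14.3. By the 2185 strongest summits alone 15 of 93 were bound, which was not past the threshold (odds ratio 1.80, adjusted exact p = 0.0904). Mitochondrial ribosomal protein genes, 18 of 73 bound, included stronger peaks at mRpL23 (1184), mRpL41 (921), mRpS10 (782) and mRpS23 (776). They did not differ from other genes by Fisher's exact test (odds ratio 1.41, adjusted p = 0.268), but exceeded matched lists (5.87 on average, adjusted permutation p = 0.0018). With each summit given to its nearest gene only, 6 of 73 were bound, which was fewer than among other genes (odds ratio 0.387, adjusted exact p = 0.0306).

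A further 9 lists were not called by Fisher's exact test. These were trithorax group (6 of 16, with brm at 517 and Trl, which encodes GAGA factor, at 303), neurogenic and proneural (5 of 27, with pros at 1260, repo at 462 and elav at 442) and cell cycle genes (9 of 31, with Dp at 218 and geminin at 158). General transcription factors and polymerase subunits (8 of 24, with Polr2F at 206 and Polr2B at 191), heat shock genes (6 of 20, with Hsp27 at 385, Hsc70-3 at 261 and Hsp83 at 237) and translation factors (15 of 52, with eIF6 at 749 and eIF4H1 at 640) were likewise not called. The same held for proteasome (5 of 32, Rpn6 at 157), respiratory chain (11 of 84, ND-ASHI at 264) and vacuolar ATPase genes (8 of 33, Vha16-5 at 204). Adjusted p-values for these 9 lists ran from 0.112, for translation factors, to 1. Some were called more often bound under other settings: trithorax group genes by the 2185 strongest summits (odds ratio 5.60, adjusted exact p = 0.00845), in replicate 1's own list (0.0358) and by nearest gene (0.0267), general transcription genes in the optimal list (0.0233) and with the missing peaks put back (0.0496), translation factors in replicate 1's own list (0.0317) and with those peaks put back (0.033), and cell cycle genes by nearest gene (0.0434). Respiratory chain genes were called less often bound by nearest gene (0.017).

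Chemoreceptor, cuticle and protease genes were rarely bound. None of 59 odorant receptor genes was bound, which allows a share of up to 6.11% (adjusted Fisher p = 3.46e-05). Of 60 gustatory receptor genes only Gr97a was bound (142, 495 bp from its TSS; adjusted exact p = 3.44e-04), and of 124 cuticle protein genes only Cpr51A (141) and Cpr11A (118; adjusted exact p = 3.03e-08). None of 27 Jonah and trypsin protease genes was bound (adjusted exact p = 0.0113). Among 85 genes of the cytochrome P450 list 5 were, including Cyp6v1 (544), Cyp18a1 (288) and Cyp6u1 (206; adjusted exact p = 0.00296); a member named Cyp1 (414) encodes a cyclophilin. Of 51 odorant-binding protein genes only Obp99b was (89.3; adjusted exact p = 0.00163). None of 111 replication-dependent histone genes was bound (adjusted exact p = 1.23e-09), but the repeated histone array on 2L, 21416953 to 21541681, held 0 summits even in the ranked lists, where 24.7 and 55.8 would be expected from its length in replicates 1 and 2. Whether a peak could have been called in that array is unknown, so its count of 0 does not show absence of binding. Against matched lists the protease and odorant-binding lists were no longer called, and the other 5 were. Members of these families lie in clusters and are not independent. With 1 gene kept per 10 kb the protease (0 of 10 bound), P450 (5 of 58, odds ratio 0.404) and histone lists (0 of 12) were no longer called. Fewer genes were tested there, so these lost calls do not show that the low shares rest on clustering. By the 2185 strongest summits the protease and P450 lists were not called either (adjusted exact p = 0.157 and 0.2), nor was the protease list within 200 bp (0.0553).

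The Hox gene abd-A had a summit at its own start and a stronger one 17331 bp upstream, and further summits lay in the bithorax complex, 1 of them within the extent of Ubx. The complex, here 3R from 16656623 to 16972236 with the genes Ubx, abd-A and Abd-B, held 22 summits, 13 of them more than 5 kb from a TSS. Ubx, named after its values were seen, had no summit within 500 bp of a TSS.

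**Figure D3:**
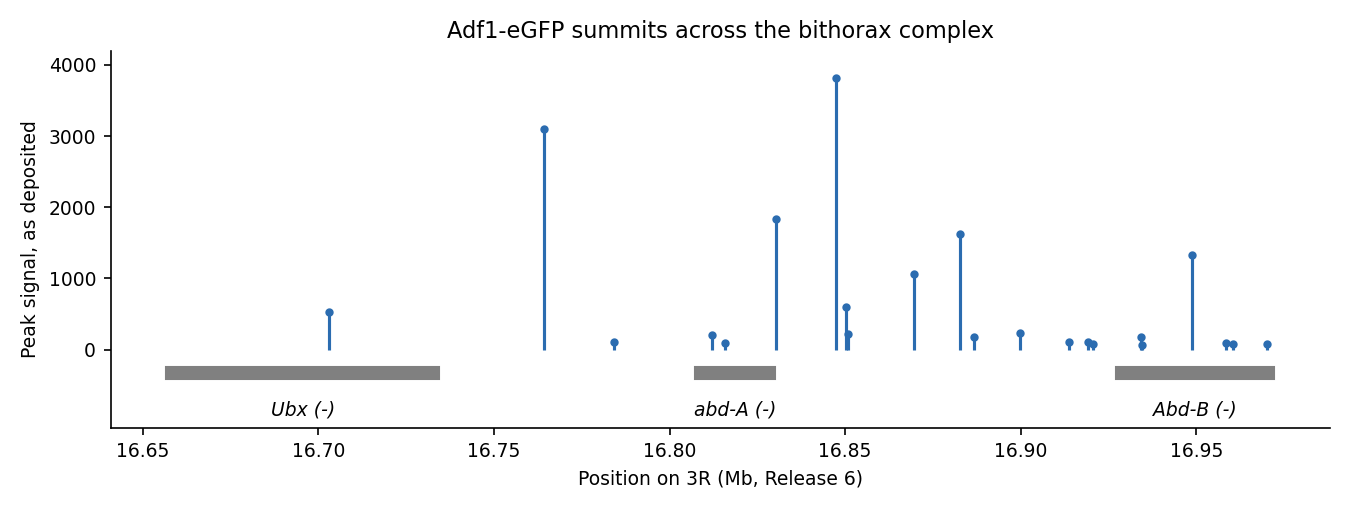
Signal of each of the 22 replicate-supported summits (vertical lines with dots) by position on 3R in Mb over the bithorax complex, with the annotated extents of Ubx, abd-A and Abd-B. The strongest, 3814, lies 17331 bp upstream of abd-A, and the summit at the start of abd-A has a signal of 1834.

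Sequence at the summits was compared with flanks 500 bp away to ask which sequences mark Adf1 binding. The triplet repeat known for Adf1, GYYGYYGYYG, occurred near the summits of Adh (GCTGCCGTCG), Eglp4 (GCTGCTGCTG), Psc (GTCGCTGCCG) and CG3036 (CGACGGCAGC, on the other strand). It was in 678 of 4370 summit windows (15.5%) and 4.77% of flanks, an odds ratio of 3.67 (3.22 to 4.17; Fisher's exact test, two-sided, adjusted over 17 motifs, p = 1.04e-89). A GCC-repeat form was in 2.04% against 0.435% (odds ratio 4.76). Motifs of other factors were also more frequent at summits: GAGA repeats in 5.65% against 2.59%, the Zeste-type sequence YGAGYG in 22.6% against 14.9%, GT repeats in 8.99% against 5.24%, a CTCF-type sequence in 4.39% against 2.12%, the E-box CAGCTG in 6.84% against 4.37% and an Sp1/KLF-type sequence in 2.43% against 1.20%. The core promoter elements DRE (1.56% against 0.423%) and M1BP (0.984% against 0.275%) were more frequent too, with odds ratios of 3.72 and 3.61. In all 10 of 17 motifs were higher and 0 lower; those of Zelda and Pho, the E-box CACGTG, TATA, Inr, STAT and AT repeats were not called. GC content was 46.0% at summits and 41.5% in flanks, and all 10 stayed higher against genomic windows of equal GC content.

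Promoter summits were also set against promoters of unbound genes. The triplet was in 13.9% of 2544 promoter summits and 2.44% of unbound promoters (odds ratio 6.45, 5.22 to 7.96), and GAGA repeats in 4.91% against 1.87%. DRE (2.56% against 2.42%) and M1BP (1.61% against 1.83%) no longer differed. TATA (5.19% against 7.63%, odds ratio 0.663) and Inr (23.0% against 25.9%) were less frequent at bound promoters.

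Of 2080 6-mers tested, those called and in at least 2% of summit windows were ranked by odds ratio. The leading sequences were GACGTC, in 8.49% of summit windows against 1.09% of flanks (odds ratio 8.44, 6.72 to 10.6), and GTCGAC, in 8.44% against 1.09% (odds ratio 8.39). Both read the same on either strand. ACGTCG, CGACGC and CGCTGC followed with odds ratios of 5.77, 5.33 and 4.88, the last in 23.9% of summit windows. CGTCGC, GACGCC, CGGCAG, ACGCCG and CGTCGA completed the leading 10, the last with an odds ratio of 4.16. In total 362 6-mers were higher and 663 lower at summits (Fisher's exact test, adjusted over all 6-mers). Neighbouring 6-mers overlap, so these counts are not of independent sequences.

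The strongest summits carried the triplet most often. It was in 344 of the 1092 strongest summits (31.5%), such as those at Eglp4, ftz-f1, not and brk, and in 80 of the 1092 weakest (7.33%), an odds ratio of 5.82 (4.48 to 7.55; Fisher's exact test, two-sided, adjusted over 2 motifs, p = 2.19e-48). In 4 classes of falling signal the shares were 31.6, 14.3, 8.88 and 7.33%. GAGA repeats were in 7.51% of the strongest and 4.85% of the weakest (odds ratio 1.59, 1.11 to 2.27, adjusted exact p = 0.0126). The GAGA difference did not hold among the stronger 2185 summits alone (odds ratio 1.27, adjusted exact p = 0.361) or after peaks missing from the final list were put back (1.41, adjusted exact p = 0.0516).

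**Figure D4:**
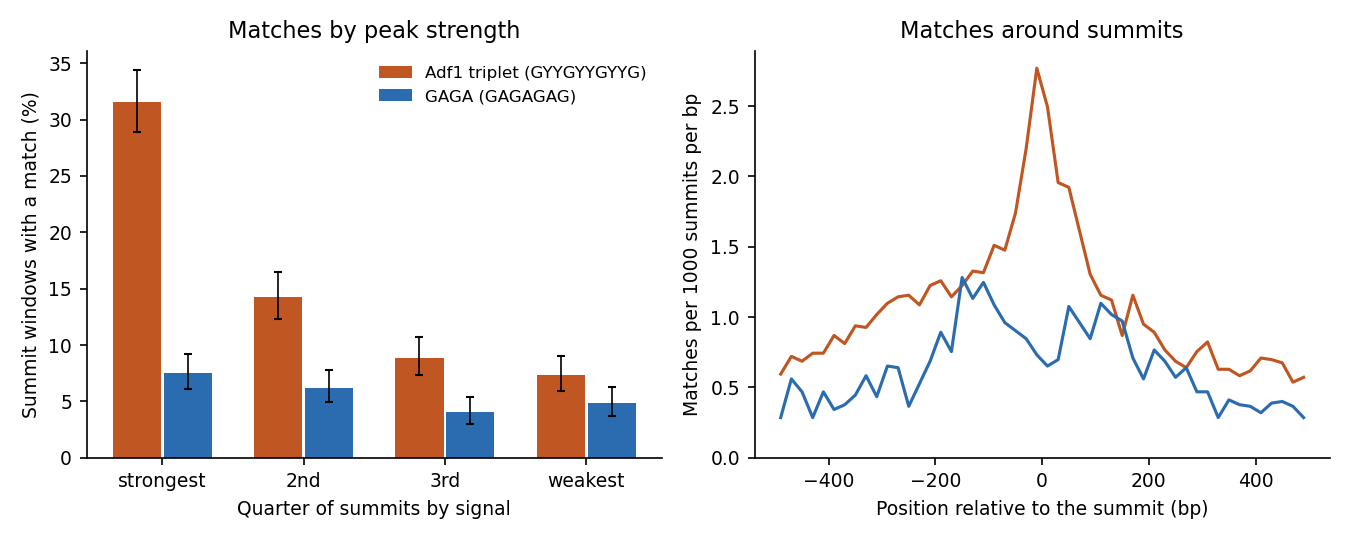
Left: percent of summit windows with the triplet and with GAGA repeats in 4 classes of falling peak signal, with 95% Wilson intervals; the triplet falls from 31.6 to 7.33%. Right, in the same colours: matches per 1000 summits and bp by position in bp around the summit, where the triplet is concentrated at the summit. GAGA repeats are lower at the summit than 100 to 160 bp to each side.

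Peaks called in 1 replicate only, those that overlapped no peak of the other's list, were compared with those called in each. By a different rule, replicate 1's list had no summit within 100 bp of that at Fas2. Replicate 2's had none within 100 bp of those at geminin and Hsc70-5. Whether these peaks overlapped one of the other list is not given. The triplet was in 7.55% of the 331 peaks of replicate 1 only against 18.9% of the others (Fisher's exact test, two-sided, adjusted over 18 quantities, p = 8.03e-07). It was in 9.15% of the 2843 peaks of replicate 2 only against 18.8% (adjusted exact p = 7.10e-26). Peaks of 1 replicate only were more often weak ones, and in the replicate-supported list the triplet share fell with signal from 31.6 to 7.33%. The comparison was not matched on signal, so peak strength was not separated from it. In replicate 1 the GCC form (0 against 2.18%), GAGA (1.81 against 5.26%), GT repeats (4.53 against 9.05%) and the Zeste-type sequence (14.2 against 22.5%) were rarer as well, so that 5 of 18 quantities differed there and 1 in replicate 2. Among peaks absent even from the other replicate's ranked list, of which 35 remained in replicate 1 and 406 in replicate 2, none of replicate 1's 5 differences was called, which so few peaks leave open, and the triplet difference of replicate 2 was still called (odds ratio 0.411, adjusted exact p = 2.51e-05). The share near a TSS did not differ (55.6 against 58.5% and 55.0 against 58.2%; adjusted exact p = 0.476 and 0.138).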

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

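All tests in this part on Adf1, on ribosomal protein genes against other genes and on the omitted peaks were chosen only after the result was seen, while the matched gene lists were planned but read for these patterns afterwards. The series has 1 group, so no explanation was tested by comparing groups.

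A signal appeared in peaks that the comparisons of the report do not use. In the ranked list, 163 peaks had a score at or above the minimum of the replicate-supported list and were missing from it. They included peaks at tara (29 summits on 3R from 16224097 to 16255494), at E2f1 and InR, at spen and at stau, the last a known target counted as not bound in the report. Their median signal was 170.2 and their highest 2049, and 102 of them were on 3R and 42 on 2L. The tables argue against unspecific peaks as the whole set, since 16.8% of the omitted summits held the triplet match against 5.59% of their own flanks. The difference was 11.2 percentage points (3.75 to 17.4 when whole runs were resampled). The omitted peaks formed 58 runs along the chromosomes, against 155 on average and at least 146 in 1000 shuffles. Removal of whole regions by the authors, whose thresholded lists were made with 1 further file that was not used here, could give this. Removal of a region from both thresholded lists would not account for stau, however. The optimal list held a summit near its TSS with a signal of 86.2, the value also found with the omitted peaks put back. Only 15 of the 58 runs held a triplet match, so unspecific peaks in the other runs stay open.

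The strongest peak lay over Adf1, the gene that was tagged. The highest ranked signal elsewhere in the gene body was 92.0, at 2R position 6666029, 88.0-fold below the main peak. Extra copies of the gene without binding stay open all the same, since that summit lies outside the coding blocks, the 2 of 4 blocks outside the main peak held no ranked summit and so no value, and the labels do not give the extent of the fusion gene. Extra copies that raise the signal of a bound site remain open too: the main peak was 2.12 times the next strongest, near abd-A, a ratio that a copy number change could give, and no copy number was measured. The main peak held 2 triplet matches (0.858 per kb, against 1.52 per kb in all peaks) and 3 matches to the palindromes GACGTC or GTCGAC.

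Longer genes with more start sites have more chances of a summit, and this could raise the share of bound genes in a list. In the main list the tables argue against it as the whole cause for Polycomb-target regulators such as mid and vg (32 bound against 13.5 on average in matched lists), ribosomal protein genes (46 against 14.3) and the 7 MADF genes (5 against 1.58), although the excess of the last was not past the threshold in the optimal list or in replicate 1's own. For synaptic and axon guidance genes such as Fas3 and Csp it may account for the whole excess, since matched lists held 15.02 bound genes and the list 14. For 6 other lists, namely known targets, Hox, Polycomb group, gap and pair-rule, glycolysis and signalling genes, the count was above the matched mean but not past the threshold, so it stays open. Ribosomal protein genes were bound more often than 7 other lists of widely used genes together (73 of 311, 23.5%, odds ratio 3.19, 1.97 to 5.18). They were bound more often than 5 of the 7 singly, from 2.41 (1.17 to 4.98) for translation factors to 6.50 (3.06 to 13.8) for the respiratory chain. Some of these lists hold extra gene copies such as COX4L, ND-24L and Vha100-3, none of them bound, which need not be widely expressed. The proteasome list, without such copies, gave 5.29 (1.87 to 14.9). The values argue against equal binding at the genes of these lists. Whether this holds among widely expressed genes alone was not tested. The interval held 1 against general transcription (1.957, 0.764 to 5.02) and glycolysis genes (0.612, 0.186 to 2.01), and a dependence on the level of expression, which was not measured, stays open.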

How the results depend on the processing

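The tests, lists, motifs and most alternatives were chosen before the data were examined; putting back the omitted peaks, keeping 1 gene per 10 kb of each list, and lists without cyclophilins or without Adf1 were chosen after seeing them. Leaving aside the named genes, many of whose values are fixed by construction, of 322 tested values under the alternatives fixed then 278 were called in the same direction or still not called. A further 26 lost the call, 12 gained it and 6 changed direction. None of these 6 was called in both directions. Of them, 2L, 2R, mitochondrial ribosomal proteins and TATA gained a call, and synaptic genes and M1BP lost theirs. From 1 replicate's list alone 120 of 128 were called in the same direction or still not called, and 137 of 145 under the added alternatives. Of untested values, 25 of 40, 13 of 14 and 11 of 12 stayed within 1.5-fold of a main count or the 95% interval of a share or correlation. The share of summits within 500 bp of a TSS stayed between 56.7 and 58.5% in all other lists. Of 99 named genes bound in the main list, 84 were bound by the 2185 strongest summits, 97 in replicate 2's list and 93 in replicate 1's. No paired analysis was possible because there is 1 group, and without read counts the effect of depth was not measured.

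Where a value changed, the cause was not tested unless given. Among the 2185 strongest summits, a number set by that choice, 2 motifs were lower (STAT and AT repeats) and the odds ratio of GAGA repeats by strength was 1.27. With the omitted peaks put back it was 1.41, and 3R was 0.988 of expected. Replicate overlap, looser or stricter by construction, was 68.7 and 39.1% for replicates 1 and 2 with 50% reciprocal overlap, 81.0 and 42.2% for summits within 100 bp and 95.8 and 54.5% among stronger peaks; the Pearson correlation of log2 signal was 0.81 in place of a Spearman correlation of 0.706. Against TSS number, 2L was 0.924 and 2R 0.918 of expected. Lists bound more often fell from 10 to 4 within 200 bp. Against matched lists 3 of the 10 were kept and mitochondrial ribosomal proteins were newly called, 4 in all, while synaptic genes such as Fas3 stood at 0.932 of the matched mean. Lists bound less often fell from 7 to 4 with 1 gene per 10 kb, where fewer genes were tested. With nearest-gene assignment mitochondrial ribosomal proteins such as mRpL23 had an odds ratio of 0.387. Lower motifs numbered 1 in the optimal list, 2 in windows of 100 bp and 2 against unbound promoters, namely TATA (odds ratio 0.663) and Inr (0.853). There M1BP had an odds ratio of 0.88 and was not called. Against the other replicate's ranked list 0 quantities differed for peaks of replicate 1 only. With 1 replicate's list alone, 3R ranged from 0.916 to 0.959 of expected and lower motifs from 0 to 1.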

Other observations

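All tests in this part were chosen only after the results of the report were seen.

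A hypothesis from the leading 6-mers was that summits at which the triplet is missing carry a second sequence. GACGTC or GTCGAC was in 321 of 3692 summit windows without the triplet (8.69%) and in 162 of 8323 such flanks (1.95%). The odds ratio was 4.80 (3.95 to 5.82), an excess that the hypothesis calls for. The palindromes were, however, more frequent where the triplet was present, in 211 of 678 summit windows. The summits tested are those on which the 6-mers were found, so the test shows only that the excess is not limited to windows with the triplet. It cannot tell a second sequence from a partial triplet site. The longer sequence CGACGTCGAC was in 153 summit windows (3.50%) and in 6 of 8740 flanks (0.0686%). Summits with both the triplet and a palindrome (GACGTC or GTCGAC) numbered 211 and had a median signal of 412.8, against 246.9 for the 321 with a palindrome only, 242.6 for the 467 with the triplet only and 137 for the 3371 (77.1%) with neither. Of the summits with both, 44.1% were within 500 bp of a TSS, against 59.5% of those with neither.

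The bithorax complex, with Ubx, abd-A and Abd-B, held 22 summits in 315.6 kb, and a hypothesis was that summits are denser there than elsewhere. Random windows of that length held 10.5 on average, and 8.33% of 10000 such windows held as many, so a denser cluster was not shown and stays open. The Antennapedia complex, with Antp, Scr and Dfd, held 9 summits against 11.2 on average, and 61.1% of random windows held as many. These bounds, 3R from 6661427 to 6999228, end at the annotated end of Antp and leave out the summits at and upstream of its start; with 5 kb added to each side there were 11 against 11.6 (53.7% of windows). Scr and Ubx were named after their values were seen.

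Summits at ribosomal protein genes such as RpL7, RpL14 and RpL41 differed in sequence from other summits near a TSS. Only 1 of 48 (2.08%) held the triplet against 14.1%, an odds ratio of 0.130 (0.0178 to 0.942; Fisher's exact test, adjusted p = 0.0385). Their median signal was lower, however (132.6 against 152.0), and summits drawn from the same classes of signal held 4.58 triplets in 48 on average (permutation p = 0.0914). A share lower than at summits of like signal was therefore not shown. A match was nonetheless present in only 1 of 48 windows (Wilson interval 0.369 to 10.9%). This argues against binding through a full triplet match within the window at most of these summits. Most other summits near a TSS lacked a match as well (14.1% held one), so this is not particular to ribosomal protein genes. Partial matches and matches farther from the summit were not tested at the ribosomal protein genes and stay open. DRE or M1BP, the core promoter elements named in the report, were in 14 of 48 (29.2%) against 3.53%, an odds ratio of 11.3 (5.84 to 21.8), and 1.90 were expected in 48 from summits of like signal (permutation p = 0.0002, the smallest possible), consistent with peaks that sit at promoters of that type. The Pho motif was also more frequent there, in 6 of 48 (12.5%) against 3.81% (odds ratio 3.61, adjusted Fisher p = 0.0385). Ribosomal protein genes without a summit were not compared, so these sequences may be as frequent at their promoters. Whether Adf1 touches DNA at the bound genes or is held there by other proteins could not be told from peak positions.

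Summits at Polycomb-target regulators such as mid, vg, fkh and dpp had a median signal of 254.8 against 150.4 at other summits near a TSS. The Zeste-type sequence YGAGYG was in 22 of 40 (55.0%) against 22.5%, an odds ratio of 4.21 (2.24 to 7.91), and 10.3 were expected in 40 from summits of like signal (permutation p = 0.0002), so this sequence may mark them, while their triplet share was 12.5% against 13.9%. YGAGYG also matches inside other short sequences, and no Zeste binding was measured. It was the only motif called among those compared at these same summits, and its permutation p was not adjusted for that choice. Polycomb-target genes without a summit were not compared, so a mark of bound sites cannot be told from a trait of these promoters.

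Summits near a TSS and the 1826 farther away differed in sequence. The triplet was in 13.9% near and 17.8% farther away (Fisher's exact test, adjusted over 17 motifs, p = 0.00149), GAGA repeats in 4.91 and 6.68% (adjusted p = 0.0338), GT repeats in 7.63 and 10.9% and a CTCF-type sequence in 3.42 and 5.75% (adjusted p = 0.00101 for each of the last pair). DRE was in 2.56 and 0.164%, and M1BP in 1.61 and 0.11%.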
